A study of Arabidopsis thaliana with 12 samples.

How the data were processed

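RNA levels were measured in 12 samples of imbibed Arabidopsis seeds, each on 1 Affymetrix array hybridised with biotinylated cRNA from total RNA, per the labels' protocols. The far-red pulse had 3.2 and the red pulse 13 umol per square metre and second, and each lasted 5 min. Samples were grouped by genotype and last light as their titles give them, into 4 groups of 3 biological replicates. The deposited table holds 22810 probe sets with log2 values between 2.867 and 14.75, normalized across arrays by the authors, as the nearly equal quantiles of the 12 columns show. The submitters' processing notes name MAS5 5.0 and RMA, and the role of each is not stated. The values were used as deposited, with no further scaling and no filter on dim probe sets, after 64 control probe sets were set aside, which left 22746. Because the table was already on the log2 scale, fits on log2(value + 1) and log2(value + 64), intended for a linear table, were not run.

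Probe sets were tied to genes by the supplied probe set annotation: 13513 had 1 gene, 503 had several and 8730 had none, and 1580 had a symbol beyond the locus tag. Of these probe sets 13436 were matched to a gene of the RefSeq annotation, which was used for names. 13356 genes had at least 1 probe set. PIL5 (AT2G20180) had 0 probe sets in this annotation. Gene lists and the rule for named genes were written before the data were examined. The rule took PIL5, then in each comparison the 5 highest and 5 lowest log2 changes among called probe sets of 1 gene with a symbol whose groups did not overlap (without the overlap rule for the interaction), then up to 4 called members of each list that was called or had 3 or more called members. All members of the GA, ABA and germination lists could be named for red in Col-0 and for pil5 in the dark.

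The comparisons were red against dark in Col-0, pil5 against Col-0 in the dark, red against dark in pil5, pil5 against Col-0 after red, and the interaction of genotype and red light. All 12 arrays were fitted together in limma 3.58.1 (R 4.3.3) with 1 mean per group and eBayes without trend, two-sided, with Benjamini-Hochberg adjustment over the 22746 probe sets and a threshold of 0.05. Lists were tested with camera in limma at a preset correlation of 0.01, on the probe set with the highest mean for each gene, adjusted over the lists of a comparison. Of 30 lists with 446 entries, 73 entries were measured and 11 lists had the minimum of 3 members. The other 19 lists were not tested, nor was a list of cytosolic ribosomal proteins, since the supplied tables hold no gene descriptions. The set called expansins includes expansin-like genes. Values simulated for unchanged groups against shared arrays came from 20 seeded draws with each probe set's own spread. Control probe sets were compared by an exact permutation test. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

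Replicates with the same number were checked for pairing. Between arrays of different groups, the deviations from the group means had r from 0.17 to 0.71 where the number was the same and from -0.68 to 0.41 where it was not, and 11 of 12 arrays correlated best with an array of their own number. The labels do not say what the number stands for. The fit without it was fixed in advance, and the fit with the number as an additive block stands beside it. Within groups the arrays correlated at r between 0.968 and 0.997.

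The fit was tested on simulated data with 100 changed probe sets of each size per comparison. It recovered 77% of 2-fold and 93% of 4-fold changes for red in Col-0, 80% and 94% for pil5 in the dark, 81% and 93% for red in pil5, 78% and 93% for pil5 after red, and 54% and 89% for the interaction. In the same order, 16 of 186, 7 of 181, 11 of 185, 10 of 181 and 8 of 151 calls were false. The list test found 100 of 100 changed lists and called 0 of 100 unchanged ones. The simulated noise was independent between genes, so this does not show how often lists whose genes vary together are called falsely. Each changed list had 10 genes, 8 of them shifted 2-fold the same way, while lists tested in the data had as few as 3 measured members. The recovery therefore says little about the smaller lists. The alternatives tried were the replicate block, fits of the 6 arrays compared, quantile normalization, median centring, leaving out the dimmest 25% or 50% of probe sets, eBayes with a trend and robust, array weights, 1 probe set per gene, a 2-fold minimum, camera with an estimated correlation, fry, and leaving out each array in turn.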

Results

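The data were gene expression values from imbibed seeds of Arabidopsis thaliana, of the Col-0 wild type and of pil5, a mutant of the phytochrome-interacting bHLH factor PIL5. Seeds received a far-red pulse of 5 min, or the far-red pulse followed by a red pulse of 5 min, and were then kept in the dark for 12 h. The 4 groups (Col-0 dark, Col-0 red, pil5 dark and pil5 red, where dark means that far-red was the last light) held 3 biological replicates each, so 12 arrays in all. Values are log2 signals of 22746 probe sets. The medians of the arrays lay between 6.082 and 6.28, and the number of arrays limits the precision of every value. All log2 changes carry the standard error of the fit (SE) with n = 3 arrays per group, and all group levels carry the SD. No probe set was tied to PIL5 in the supplied probe set annotation, so the transcript of the mutated gene could not be checked. No genome build was stated for the array, and positions are therefore not given.

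The first principal component held 41.4% of the variance and the second 32%. The Col-0 dark arrays lay apart from the Col-0 red arrays, and the pil5 dark and pil5 red arrays of numbers 1 and 2 lay close together. The third pil5 red array stood apart from the other two. Its bacterial bioC spike-in control read 7.45, while the other 11 arrays read between 8.77 and 9.21. Its bioB and bioD controls read 7.5 and 11.24, within the range of the other arrays. Its 23 mitochondrial probe sets had a median of 9.91, against 7.12 in the pil5 dark array of the same number. None of the control measures differed between groups in an exact permutation test (two-sided, p from 0.1 to 1, adjusted p = 1), for which 0.1 is the smallest p that 3 against 3 arrays allow.

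**Figure D1:**
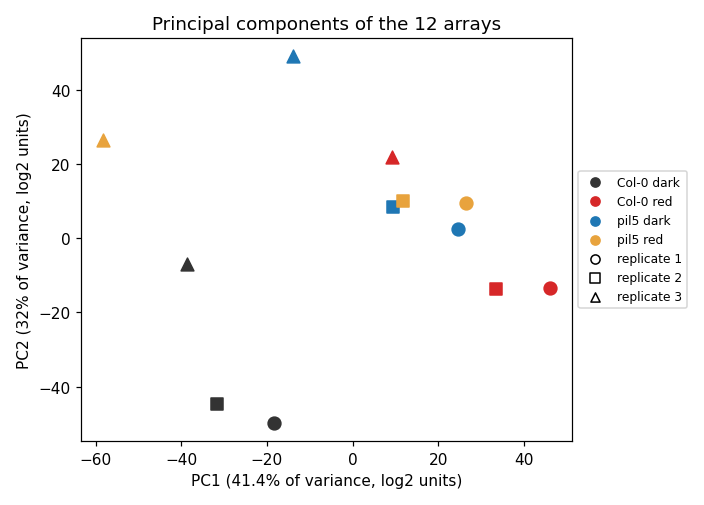
Each point is 1 of the 12 arrays on the first (41.4% of the variance) and second (32%) principal components of the log2 signals, coloured by group and shaped by replicate number. The third pil5 red array lies at -58.2 on the first component, while the other two lie at 26.53 and 11.8.

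The first comparison asked which seed transcripts differed 12 h after a red pulse in Col-0. The largest fall among genes with a symbol was that of FHL (AT5G02200), a homologue of FHY1 that acts in nuclear import of phytochrome A. It fell from 10.00 ± 0.11 to 5.10 ± 0.09 (SD, n = 3), a log2 change of -4.90 (SE 0.18, adjusted p = 8.5e-07). ALDH2C4 (AT3G24503), an aldehyde dehydrogenase of phenylpropanoid metabolism, fell by 3.03 on the log2 scale (SE 0.13, adjusted p = 2e-06). HIS1-3 (AT2G18050), a linker histone, fell by 2.96 (SE 0.41), XERICO (AT2G04240), a RING protein that promotes abscisic acid (ABA) accumulation, fell by 2.43 (SE 0.38), and the Aux/IAA gene IAA30 (AT3G62100) fell by 1.94 (SE 0.18). The largest rises were those of ASPGB1 (AT3G16150), an asparaginase, by 3.17 (SE 0.57), the serine carboxypeptidase-like gene scpl44 (AT1G43780) by 2.68 (SE 0.63), the cysteine proteinase CP1 (AT4G36880) by 2.40 (SE 0.60), the expansin EXPA8 (AT2G40610) by 2.18 (SE 0.45) and APL3 (AT4G39210), a large subunit of ADP-glucose pyrophosphorylase, by 2.17 (SE 0.58).

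Late embryogenesis abundant (LEA) and ABA-responsive genes, whose products accumulate in dry seeds, were lower after red in Col-0. Of 10 measured members 6 fell, 0 rose and 4 did not pass, and all 10 fell when adjusted over the list alone. Among the 6 were AT2G42560 (-2.21, SE 0.41), AT3G17520 (-1.49, SE 0.25), AT4G21020 (-1.23, SE 0.30) and LEA18 (-1.0, SE 0.28). The list had a median log2 change of -1.06 and adjusted p = 3.5e-06 (camera), and adjusted p = 0.24 with an estimated correlation. In the list of gibberellin (GA) perception and DELLA genes, 2 of 4 measured members fell, also when adjusted over the list alone. These were the GA receptor genes GID1A (-1.79, SE 0.16) and GID1C (-1.11, SE 0.14). The third receptor gene GID1B had a log2 change of 0.15 (SE 0.29, adjusted p = 0.84). Its group means lay between 4.61 and 4.93, against 10.58 for GID1A in Col-0 dark, a low signal at which a fall could hardly be seen. SLY1, the F-box gene of DELLA turnover, had -0.44 (SE 0.23, adjusted p = 0.26, and 0.0022 with the replicate number as a block). No DELLA gene was among the 4 measured members, so here and below the list says nothing of DELLA transcripts. The list had adjusted p = 0.0066, and adjusted p = 0.11 with an estimated correlation.

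Some cell wall genes were higher after red in Col-0. Of 5 measured xyloglucan and mannan hydrolases, enzymes that modify or cut hemicelluloses, 3 rose, also when adjusted over the list alone: XTH16 by 2.09 (SE 0.42), XTH33 by 1.94 (SE 0.39) and XTH18 by 0.72 (SE 0.19). XTH18 read 3.72 in Col-0 dark and 4.44 in Col-0 red, near the lower quartile of the arrays, so its rise lay at low signal. The other measured members were XTH19 and EXGT-A3, so here and below no mannan hydrolase was measured. This list had a median of 1.94 and adjusted p = 0.0066, and adjusted p = 0.11 with an estimated correlation. The 9 genes with an XTH symbol, grouped after the data were seen, had a median of 0.16 and were not called (camera, adjusted p = 0.19 over 47 families). Of 10 expansins, which loosen cell walls, 2 rose, EXPA8 and EXPA15 (1.53, SE 0.43), and 3 rose when adjusted over the list alone. The expansins had a median of 0.43 and adjusted p = 0.026, and adjusted p = 0.24 with an estimated correlation. The 10 genes with an EXPA symbol, grouped after the data were seen, had a median of 0.34 and were not called (camera, adjusted p = 0.24 over 47 families). Of the regulators of ABA signalling and germination, 1 gene in each list was measured: EEL, a bZIP factor of the ABA response, fell by 1.72 (SE 0.50), and SPT, the bHLH factor SPATULA, rose by 1.08 (SE 0.29). The lists of photosystem and light-harvesting genes, chlorophyll synthesis, Aux/IAA and GH3 genes, storage lipid mobilisation, heat shock proteins and cold-responsive genes were called in none of the 5 comparisons by camera without the block. Their lowest adjusted p over these comparisons were 0.066, 0.31, 0.39, 0.65, 0.14 and 0.41. In the same order, 7 of 33, 3 of 15, 7 of 28, 3 of 18, 3 of 14 and 3 of 9 entries were measured. Most genes of each list were thus not tested. The heat shock list had its lowest value for pil5 after red, where it was called with the block (adjusted p = 0.027).

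**Figure D2:**
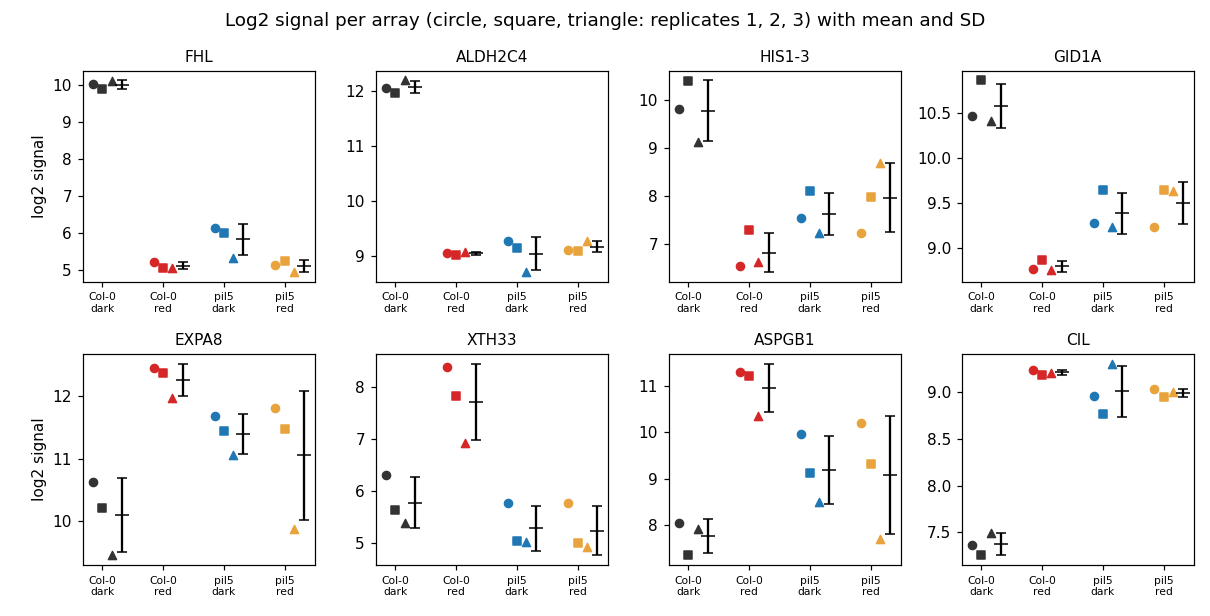
Log2 signal of 8 genes in the 12 arrays, as points by group with circle, square and triangle for replicates 1, 2 and 3, and the mean with SD beside them; each panel has its own axis. FHL lies near 10 in the 3 Col-0 dark arrays and between 5.10 and 5.82 in the means of the other groups.

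In this comparison, limma called 3443 of 22746 probe sets, 1776 higher and 1667 lower after red, and 914 of them changed at least 2-fold. Every called probe set had the same sign in each of the 3 replicate numbers, which adds little, since the calls were chosen on these same arrays. With the replicate number as a block the count was 6009 (3040 higher, 2969 lower), and it included all 3443. The count moved by more than 1.5 times without Col-0 dark 1 (2009), Col-0 red 1 (1784) or Col-0 dark 2 (1587). The calls of scpl44, CP1, APL3, EEL, AT4G21020, LEA18, SPT, EXPA15 and XTH18 ended without 1 of at least 4 arrays each (any of the 6 Col-0 arrays, pil5 dark 1 or 2, or pil5 red 2), with the sign kept and adjusted p up to 0.14, while the other 13 called genes named here passed without any 1 array.

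The second comparison asked which transcripts differed in pil5 where far-red was the last light. FHL fell by 4.18 on the log2 scale (SE 0.18, adjusted p = 2.9e-06) and ALDH2C4 fell by 3.03 (SE 0.13, adjusted p = 2.9e-06), the largest falls among genes with a symbol. The MADS-box gene AGL67 (AT1G77950) fell by 2.69 (SE 0.50), DPE1 (AT5G64860), the plastid disproportionating enzyme of starch breakdown, fell by 2.42 (SE 0.42), and EEL fell by 2.37 (SE 0.50). The largest rises were those of CP1 by 2.45 (SE 0.60), the glutathione transferase GSTU25 (AT1G17180) by 2.38 (SE 0.54), the chaperone Hsp70-2 (AT5G02490) by 2.04 (SE 0.36), the CCT-domain gene CIL (AT4G25990) by 1.64 (SE 0.12) and the chromatin remodelling gene CHR34 (AT2G21450) by 1.58 (SE 0.40).

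LEA and ABA-responsive genes were lower in pil5 in the dark: 5 of 10 measured members fell, 0 rose, and 7 fell when adjusted over the list alone. Among them were AT2G42560 (-2.18, SE 0.41), AT3G17520 (-1.17, SE 0.25), AT4G21020 (-1.09, SE 0.30) and LEA18 (-1.07, SE 0.28). The list had a median of -0.89 and adjusted p = 1.7e-05, and adjusted p = 0.39 with an estimated correlation. Of the 4 GA perception and DELLA genes, GID1A (-1.20, SE 0.16) and GID1C (-1.07, SE 0.14) fell, which were 2 also when adjusted over the list alone. GID1B, again at low signal, had 0.11 (SE 0.29, adjusted p = 0.89), and SLY1 had -0.25 (SE 0.23, adjusted p = 0.59, and 0.03 with the block). This list had a median of -0.66 and adjusted p = 0.021, and adjusted p = 0.29 with an estimated correlation. Without the third pil5 red array, 1 list was called here in place of 2. SPT had a log2 change of 0.41 (SE 0.29, adjusted p = 0.46). Neither cell wall list was called: the expansins had a median of 0.05 (adjusted p = 0.89) and the xyloglucan and mannan hydrolases 0.23 (adjusted p = 0.65).

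limma called 2750 probe sets in pil5 against Col-0 in the dark, 1384 higher and 1366 lower in pil5, of which 705 differed at least 2-fold. With the block the count was 5406 (2637 higher, 2769 lower), and it included all 2750. The count was lower without Col-0 dark 1 (982), Col-0 dark 2 (769), pil5 dark 2 (1731) or pil5 dark 3 (1355). The calls of CP1, GSTU25, CHR34, EEL, AT3G17520, AT4G21020 and LEA18 ended without 1 of at least 2 arrays each (any of the Col-0 dark, Col-0 red or pil5 dark arrays, or pil5 red 2), with the sign kept and adjusted p up to 0.15, while the other 9 called genes named here passed without any 1 array.

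Transcripts that differed in pil5 in the dark overlapped with those that differed after red in Col-0. Of these, 915 probe sets were higher in both comparisons and 997 lower in both, where independent calls would share 108 and 100. The 1912 shared probe sets were 55.5% of those called for red and 69.5% of those called for pil5, and 5 went opposite ways. FHL, ALDH2C4, EEL, GID1A, GID1C and CP1 were among the shared genes. Both comparisons used the same 3 Col-0 dark arrays. Across probe sets, which are not independent replicates, the log2 changes had r = 0.769 and a covariance of 0.16, and 75% had the same sign. Simulated unchanged groups against shared controls gave r = 0.50, a covariance of 0.0251, 66.6% of the same sign and on average 0.05 shared calls. With no true change simulated, hardly any probe set could be called. The 0.05 therefore does not show how far shared arrays raise the overlap where many probe sets differ. The 3 control arrays are too few to give each comparison at least 2 of its own, and part of the excess in the overlap may come from them. With no array shared, probe sets at least 2-fold changed by red in replicate number 1 had a median pil5 difference in number 2 of 0.87 for rises and of 1.06, in the direction of the fall, for falls. With the block the overlap was 3602. It was 761 without Col-0 dark 1, 1214 without Col-0 red 1, 1229 without pil5 dark 1, 569 without Col-0 dark 2, 1144 without pil5 dark 3 and 2890 without pil5 red 3.

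**Figure D3:**
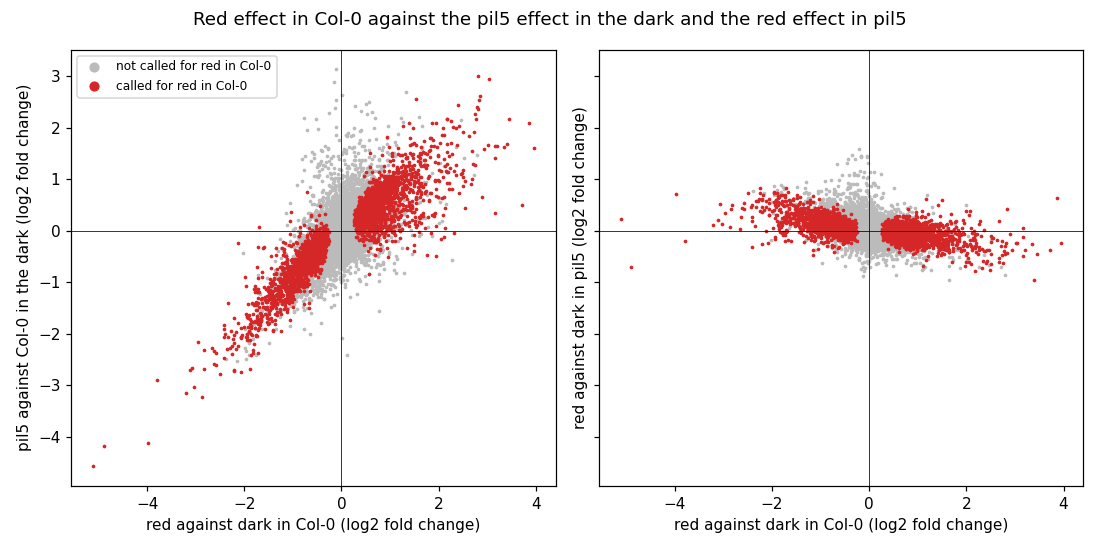
Each point is a probe set; the horizontal axis is the log2 change after red in Col-0, and the vertical axes are the log2 difference of pil5 from Col-0 in the dark (left) and the log2 change after red in pil5 (right), with the 3443 probe sets called for red in Col-0 in red. The slope is 0.719 on the left, where both axes share the Col-0 dark arrays, and -0.138 on the right.

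The third comparison asked for the red effect in pil5 seeds. FHL had a log2 change of -0.71 (SE 0.18), ALDH2C4 of 0.12 (SE 0.13), GID1A of 0.12 (SE 0.16), EXPA8 of -0.34 (SE 0.45) and ASPGB1 of -0.11 (SE 0.57), each with adjusted p = 1. limma called 0 probe sets (267 at an unadjusted p below 0.05), and 0 with the block (692 unadjusted), where the smallest adjusted p was 0.92. The third pil5 red array carried most of the large differences: 958 probe sets differed at least 2-fold from the pil5 dark array of its number, against 1 and 0 in numbers 1 and 2. The LEA and ABA-responsive list was called higher after red (median 0.46, adjusted p = 1.5e-06), and adjusted p = 0.43 with an estimated correlation. Of its members 0 of 10 passed, also 0 when adjusted over the list alone, and its median by replicate number was -0.14, 0.10 and 1.51, so the call rested on the third pil5 red array. Without that array 0 lists were called, and 2 were called without pil5 dark 1 or without pil5 dark 3. The slope of the red effect in pil5 on that in Col-0 was -0.138 across probe sets (r = -0.404), and by replicate number it was 0.0594, 0.0417 and -0.529. Without the third pil5 red array the slope was 0.0772, so its sign rested on that array.

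The fourth comparison set pil5 against Col-0 after red. Genes with a symbol that passed and did not overlap between the groups all fell. XTH33, a xyloglucan hydrolase, fell by 2.48 (SE 0.39, adjusted p = 0.042), from 7.71 ± 0.73 to 5.23 ± 0.47 (SD, n = 3). The thaumatin-like gene ATLP-1 (AT1G18250) fell by 1.95 (SE 0.32) and the methionine sulfoxide reductase MSRB9 (AT4G21850) fell by 1.63 (SE 0.16). The beta-glucosidase BGLU28 (AT2G44460) fell by 1.47 (SE 0.21) and the glutathione transferase GSTU27 (AT3G43800) fell by 1.36 (SE 0.14). Of the xyloglucan and mannan hydrolases 1 of 5 fell, and 2 fell when adjusted over the list alone. Their list had a median of -1.34 and adjusted p = 0.0022, and adjusted p = 0.15 with an estimated correlation. The genes with an XTH symbol, grouped after the data were seen, had a median of only -0.13 (2 higher, 7 lower). The median of the list was -0.72, -0.64 and -2.00 in replicate numbers 1, 2 and 3. Of 10 expansins 0 passed (4 fell with the block, and 3 fell when adjusted over the list alone), with a median of -0.36, adjusted p = 0.0022, and adjusted p = 0.17 with an estimated correlation. Of 7 tubulins, the subunits of microtubules, 0 passed (3 fell with the block, and 3 when adjusted over the list alone), with a median of -0.62, adjusted p = 0.0022, and adjusted p = 0.22 with an estimated correlation. The LEA and ABA-responsive list was called higher in pil5 with 0 of 10 members past the test, also 0 when adjusted over the list alone. It had a median of 0.61, adjusted p = 9.8e-05, and adjusted p = 0.28 with an estimated correlation, and its median was 0.39, 0.41 and 1.07 in replicate numbers 1, 2 and 3. Another 2 lists were called higher in pil5 with the block and not without it, all 12 arrays used. They were the GA perception and DELLA genes (median 0.16, adjusted p = 0.069, and 0.023 with the block, but adjusted p = 0.18 with the block and an estimated correlation) and the heat shock proteins (median 0.78, adjusted p = 0.14, and 0.027 with the block, but adjusted p = 0.35 with the block and an estimated correlation). The heat shock median was 0.06, 0.40 and 2.05 by replicate number, so it was largest in number 3, which holds the pil5 red array that stood apart. Without that array both lists had adjusted p = 0.087 with the block.

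limma called 44 probe sets in the fourth comparison, 9 higher and 35 lower in pil5, and 1880 with the block (811 higher, 1069 lower), which included all 44. When limma was fitted to only the 6 arrays compared, 0 were called (2255 at an unadjusted p below 0.05). With the block and 1 array left out the count was between 559 (without Col-0 red 2) and 2447 (without Col-0 dark 3). In the fit of all arrays without the block it was 16 without Col-0 dark 1, 3 without Col-0 red 1, 29 without Col-0 dark 2, 9 without Col-0 red 2, 17 without pil5 dark 2, 5 without pil5 red 2, 112 without Col-0 red 3, 77 without pil5 dark 3 and 28 without pil5 red 3. MSRB9 passed without any 1 array, while the calls of XTH33, ATLP-1, BGLU28 and GSTU27 ended without 1 of at least 2 arrays each (Col-0 dark 1 or 2, Col-0 red 1 or 2, pil5 dark 1 or 2, or any pil5 red array), with the sign kept and adjusted p up to 0.24.

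**Figure D4:**
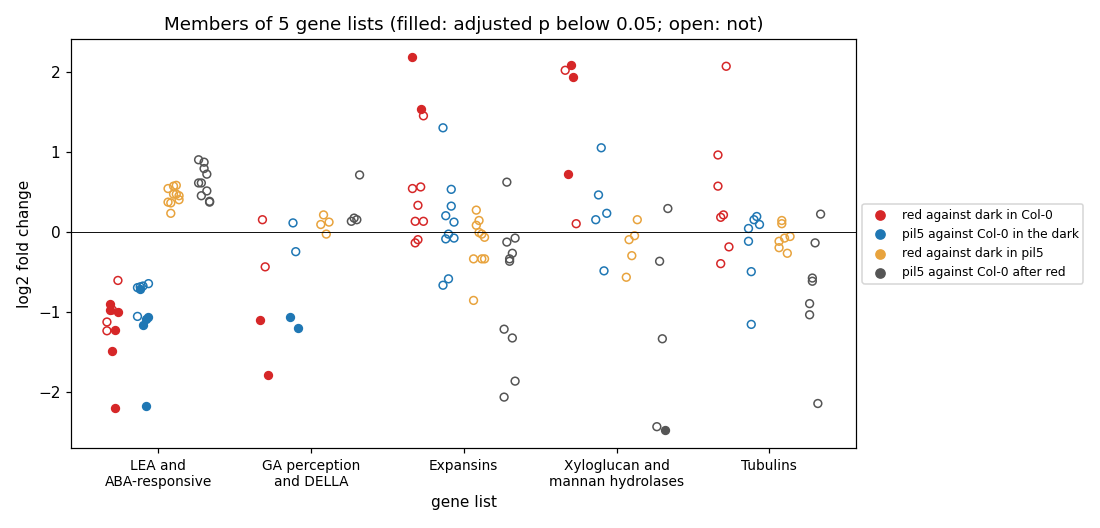
Log2 change of each measured member of 5 gene lists (horizontal axis) in 4 comparisons shown by colour, with filled points for adjusted p below 0.05 and open points for the others. All 10 LEA and ABA-responsive members lie below 0 for red in Col-0 and for pil5 in the dark, and all 10 lie above 0 for red in pil5, where 0 passed.

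The last comparison tested whether the red effect differed between pil5 and Col-0, as the pil5 effect minus the Col-0 effect. The difference was 4.18 for FHL (SE 0.26, adjusted p = 8e-05) and 3.15 for ALDH2C4 (SE 0.19, adjusted p = 8e-05), both of which fell after red in Col-0. It was 3.3 for HIS1-3 (SE 0.58), 2.89 for XERICO (SE 0.54) and 2.28 for MGL (AT1G64660, SE 0.40), a methionine gamma-lyase. Among genes that rose after red in Col-0, it was -3.28 for ASPGB1 (SE 0.80), -2.52 for EXPA8 (SE 0.64), -2.45 for scpl25 (AT3G02110, a serine carboxypeptidase-like gene, SE 0.56), -2.39 for XTH16 (SE 0.59) and -2.23 for GPDHC1 (AT2G41540, a glycerol-3-phosphate dehydrogenase, SE 0.36). Of the GA perception and DELLA genes GID1A (1.91, SE 0.23) and GID1C (1.20, SE 0.19) passed, 2 of 4 and 2 when adjusted over the list alone, and the list had adjusted p = 0.0059, and adjusted p = 0.16 with an estimated correlation.

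Of the LEA and ABA-responsive genes 4 of 10 had a higher red effect in pil5, and 10 when adjusted over the list alone. These were AT2G42560 (2.69, SE 0.59), AT3G17520 (1.96, SE 0.36), AT4G21020 (1.81, SE 0.42) and AT5G44310 (1.33, SE 0.29). The list had a median of 1.58 and adjusted p = 5.7e-08, and adjusted p = 0.21 with an estimated correlation, and its median was 1.14, 1.24 and 2.26 in replicate numbers 1, 2 and 3. Of the xyloglucan and mannan hydrolases 1 of 5 had a lower red effect in pil5, and 3 when adjusted over the list alone. Their median was -1.99 with adjusted p = 0.015, and adjusted p = 0.16 with an estimated correlation. The expansins were not called (median -0.46, adjusted p = 0.053, and 0.015 with the block, but adjusted p = 0.44 with the block and an estimated correlation).

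limma called 1443 probe sets with a different red effect, 710 higher and 733 lower in pil5, and 3973 with the block (1987 higher, 1986 lower), which included all 1443. With the block and 1 array left out it was between 1672 (without Col-0 dark 2) and 5175 (without Col-0 dark 3). In the fit without the block the count was 197 without Col-0 dark 1, 68 without Col-0 red 1, 325 without pil5 dark 1, 76 without Col-0 dark 2, 635 without Col-0 red 2, 879 without pil5 dark 2, 898 without pil5 red 2, 620 without Col-0 red 3 and 599 without pil5 dark 3. Without pil5 dark 3, 5 lists were called in place of 3. FHL, ALDH2C4 and GID1A passed without any 1 array, while the calls of the other 13 genes named for this comparison ended without 1 of at least 2 arrays each (most often Col-0 dark 1, Col-0 red 1 or Col-0 dark 2, and for at least 1 gene each of the others except pil5 red 1), with the sign kept and adjusted p up to 0.11.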

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

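The test of the difference between the red effects was planned, while the counts over other splits and all tests of explanations in this part were chosen after the results were seen. The red effect differed between pil5 and Col-0 in 1443 probe sets by the interaction term, which tests the difference itself. The median difference, pil5 minus Col-0, was 0.80 for GA perception and DELLA genes, 1.58 for LEA and ABA-responsive genes and -1.99 for xyloglucan and mannan hydrolases. By gene it was 4.18 for FHL, 3.3 for HIS1-3, 3.15 for ALDH2C4, 2.89 for XERICO, 2.28 for MGL, 1.91 for GID1A and 1.20 for GID1C. It was 2.69 for AT2G42560, 1.96 for AT3G17520, 1.81 for AT4G21020 and 1.33 for AT5G44310. It was -3.28 for ASPGB1, -2.52 for EXPA8, -2.45 for scpl25, -2.39 for XTH16 and -2.23 for GPDHC1. Of 100 regroupings of the 12 arrays, 1, the real one, gave as many probe sets for the interaction, and the highest of the others gave 526. Regrouping mixes the effects of red and of genotype into the spread within groups. It can give few calls for that reason alone, so neither this count nor those below exclude chance for the interaction. Of 100 regroupings that keep 1 array of each replicate number in each group, 2 gave as many, the real one included, and the highest of the others gave 2102. That one differs from the real grouping only in an exchange of the pil5 dark and pil5 red arrays of number 1. With the block 2 of 100 gave as many as the real 3973, and the highest of the others gave 4648. Without the block the count itself was as low as 68 when 1 array, Col-0 red 1, was left out, and 76 without Col-0 dark 2. With the block it was 2076 without Col-0 red 1 and 1672 without Col-0 dark 2.

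The 10 splits of 6 arrays are too few for a share under 0.05. For red in Col-0 the real split gave 3443, for pil5 in the dark 2750 and for pil5 after red 44, and the highest of the other splits gave 0 in each, so that 1 of 10 splits reached the real count. For red in pil5 all 10 splits gave 0. The replicate numbers pair the arrays, and the other splits that part all 3 pairs also gave at most 0 calls. The rest part 1 pair only and keep the arrays of the other numbers together.

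The third pil5 red array stood apart from the other pil5 red arrays, with 958 probe sets at least 2-fold from the pil5 dark array of its number. Of all arrays it correlated best with Col-0 dark 3 (r = 0.986). It had r = 0.981 with pil5 dark 3, and 0.968 and 0.975 with pil5 red 1 and 2. A mixture with RNA of Col-0 dark seeds, as the whole cause, would place its values between those of the pil5 dark and Col-0 dark arrays, but 251 of the 958 lay at least 2-fold outside both. The other numbers give no scale for this count, since only 1 and 0 of their probe sets differed 2-fold from pil5 dark at all. Degraded RNA was argued against by the 3' minus 5' difference of actin, which was -0.01 from that of the pil5 dark array of number 3. Carry-over of all RNA without a poly(A) tail would raise plastid transcripts, whose median change was -0.20 (23 of 69 higher), while 23 of 23 mitochondrial transcripts were higher (median change 2.70) and 25S rRNA read 11.21 against 5.93, which carry-over would give. No biological explanation was tested, since the design sets this array apart in no way, and an event in this sample alone stays open.

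The third array of every group was low in the 69 plastid-encoded probe sets, by -1.61 in Col-0 dark, -1.35 in Col-0 red, -1.73 in pil5 dark and -1.99 in pil5 red against the mean of the other two. Less carry-over of RNA without a poly(A) tail would lower mitochondrial transcripts too, but these were higher in each group, with 0.13 as the lowest difference, and 25S rRNA was higher by 2.85 in pil5 red. The 25S rRNA was lower in the other groups (-1.48 in Col-0 red, -1.61 in pil5 dark and -4.53 in Col-0 dark, where the third array read 5.65 against 7.46 and 12.9, so that its size rests on Col-0 dark 2), which less carry-over would give, so these values argue against less carry-over of all such RNA alike, while less of rRNA and plastid RNA alone stays open. Degraded RNA cannot be told apart from other causes here: the 3' minus 5' difference of actin was higher in the third array of each group, with 0.13 as the lowest of 4 differences and 0.26 as the highest, which is too small to decide. What the replicate number stands for is not stated, and a difference in the seeds or in the handling of that replicate stays open and untested.

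Some probe sets were called both for red in Col-0 and for pil5 against Col-0 after red. Of these, 33 that rose after red were lower in pil5 and 5 that fell were higher, and 0 went the same way. With the block 657 that rose were lower and 373 that fell were higher, while 32 that rose were higher and 25 that fell were lower. The 2 comparisons share the Col-0 red arrays with opposite signs, and unchanged groups simulated so gave r = -0.497 against the observed -0.594 and 33.4% of the same sign against 30.4%. For probe sets at least 2-fold higher after red in replicate number 1, the median difference of pil5 from Col-0 after red in number 2 was -0.37, with 610 of 744 lower, and for those at least 2-fold lower it was 0.17, with 510 of 732 higher, measures that use none of the choosing arrays. The third pil5 red array alone was argued against by the fit with the block and without it, which called 2183 probe sets: of those that rose after red in Col-0 659 were lower and 134 higher in pil5, and of those that fell 401 were higher and 145 lower. The interaction term called 1443 probe sets, and 1437 of these were also called for red in Col-0 with the opposite sign. For these the measured red effect in the direction of Col-0 was smaller in pil5. Part of the opposite signs is built in, since both comparisons use the Col-0 arrays. What made the red effect differ was not tested, and unknown differences between the seed lots stay open.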

How the results depend on the processing

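The fit with the block and without pil5 red 3, replicates 1 and 2 alone, a random block for the replicate number and the block with an estimated correlation were added after seeing the data. Counts are given for red in Col-0, pil5 in the dark, pil5 after red and the interaction, in this order. The replicate block gave 6009, 5406, 1880 and 3973, a random block 5411, 4734, 786 and 3411, array weights 7549, 7008, 2800 and 5242, the block without pil5 red 3 gave 7785, 7377, 2183 and 4086, and replicates 1 and 2 alone 7107, 6299, 1586 and 3874. With 1 probe set per gene, which tests fewer probe sets, they were 1940, 1555, 16 and 834. A 2-fold minimum left 914, 705 and 752 for red in Col-0, pil5 in the dark and the interaction, by its construction. For pil5 after red the count was 0 with only the 6 arrays compared, 72 with median centring and 12 without the dimmest 50%. The overlap of the red and pil5 calls was 3602 with the block, 4744 in replicates 1 and 2 alone and 5179 with the block and without pil5 red 3. Lists called were 0 in each of the 5 comparisons with an estimated correlation, with and without the block. fry called 0 lists for red in pil5 and 1 for pil5 after red, and it called the photosystem list for pil5 in the dark (adjusted p = 0.027). Replicates 1 and 2 alone called 1 list for pil5 in the dark and 0 for red in pil5, where the LEA and ABA-responsive list turned to lower (adjusted p = 0.89), and the block without pil5 red 3 also called 0 there. Where no cause is named, the cause was not tested. Without the block, leaving out 1 array gave 1587 to 4668 for red in Col-0, 769 to 3965 for pil5 in the dark, 0 to 0 for red in pil5, 3 to 112 for pil5 after red, 68 to 2104 for the interaction and 569 to 2890 for the overlap. It gave a slope of pil5 on Col-0 red effects from -0.291 to 0.0772, against 0.0517 in replicates 1 and 2 alone and 0.0702 with the block and without pil5 red 3. The sign of the slope, -0.138 with all arrays, thus depends on the third pil5 red array. Lists called were 3 to 4, 1 to 2, 0 to 2, 4 to 6 and 3 to 5 for red in Col-0, pil5 in the dark, red in pil5, pil5 after red and the interaction. Red in pil5 had 0 calls in every alternative. Quantile normalization, leaving out the dimmest 25% and eBayes with a trend and robust moved none of the 5 counts by over 1.5 times. Of 64 results, each for 1 gene in 1 comparison and called or not, 62 stayed on their side of the threshold with the block, and SLY1 passed in 2 comparisons. The block ended none of 14 list calls and added 2 for pil5 after red (GA perception and DELLA, and heat shock proteins) and 1 for the interaction (expansins). With quantile normalization 63 of the 64 results stayed on their side and 1 call was lost. Leaving out 1 array kept the side of the threshold in 595 such values and ended the call in 173, with no change of sign among the called genes. Signal near the background limits what dim probe sets can show.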

Other observations

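The gene families and the test in this part were chosen after the data were seen. Genes were grouped into 47 families by symbol. After red in Col-0, genes of autophagy (ATG) were lower: 3 of 8 fell, ATG8F (-1.23, SE 0.17), ATG8C (-0.92, SE 0.13) and ATG8D (-0.85, SE 0.19), with a family adjusted p = 0.04, and adjusted p = 0.92 with an estimated correlation. CRR genes, which act in plastid RNA editing and in assembly of the plastid NDH complex, were higher: 3 of 5 rose, CRR28 (0.85, SE 0.24), CRR41 (0.83, SE 0.17) and CRR22 (0.49, SE 0.12), with adjusted p = 0.044, and adjusted p = 0.92 with an estimated correlation. In pil5 in the dark, 8 of 8 aldehyde dehydrogenase (ALDH) genes were lower and 2 of them fell, ALDH2C4 (-3.03, SE 0.13) and ALDH10A9 (-0.59, SE 0.10), with adjusted p = 0.00026, and adjusted p = 0.92 with an estimated correlation. After red, 7 of 8 ATG genes (adjusted p = 0.00079) were higher in pil5 than in Col-0. There 5 of 5 CRR (adjusted p = 0.0032), 5 of 5 TUB (adjusted p = 0.0045), 22 of 29 SCPL (adjusted p = 0.0096), 7 of 9 XTH (adjusted p = 0.023) and 9 of 10 EXPA genes (adjusted p = 0.032) were lower. The medians were lowest in number 3 for EXPA (-0.22, -0.18 and -0.53) and XTH (-0.07, -0.14 and -0.43). Of these genes 1 XTH passed by itself, and the families had adjusted p from 0.47 to 0.58 with an estimated correlation. After red in pil5, 5 of 5 CCB (adjusted p = 0.0046) and 8 of 8 NAD genes (adjusted p = 0.0061) were higher with 0 past the test, and adjusted p = 0.85 and adjusted p = 0.96 with an estimated correlation. By replicate number the medians were 0.07, 0.04 and 1.9 for CCB and -0.06, -0.06 and 2.59 for NAD, so both calls rested on number 3, which holds the pil5 red array that stood apart. The medians of all these families had the same sign with quantile normalization and with median centring, and 3 ALDH genes fell with the latter.

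Among single genes of lists with too few members to test, the ethylene factor EIN3 fell after red in Col-0 by 0.74 (SE 0.12, adjusted p = 0.0039) and in pil5 in the dark by 0.51 (SE 0.12, adjusted p = 0.024). Of the photosystem genes, PSBY rose after red in Col-0 by 1.15 (SE 0.17, adjusted p = 0.0026), and RCA, the rubisco activase gene, fell by 0.46 (SE 0.10, adjusted p = 0.0097). In pil5 in the dark RCA fell by 0.62 (SE 0.10, adjusted p = 0.0048). LHCB4.1, a light-harvesting gene, fell there by 1.36 (SE 0.31, adjusted p = 0.02). ICL, the isocitrate lyase of the glyoxylate cycle, read between 14.37 and 14.43 in the means of all 4 groups, near the highest value of the table.

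A hypothesis is that pil5 seeds in the dark may hold part of the red response of Col-0. Probe sets at least 2-fold changed by red in replicate number 1 were measured in number 2, where the median ratio of the pil5 difference to the red difference was 0.77, while a ratio under 0.25 would have spoken against it. That bar was set after the data were seen, when the same arrays had already given a slope of 0.719 for pil5 on red log2 changes. The outcome could thus be foreseen, and the ratio describes a size rather than testing the hypothesis anew. The other choices of replicate numbers gave medians from 0.76 to 0.78. These medians pool rises and falls, which differed: chosen in number 1, the ratio for rises was 0.65 in number 2 and 0.45 in number 3, and for falls it was 0.84 and 1.04. The ratio divides values that share 1 Col-0 dark array, and the choice of probe sets used none of the arrays measured. With pil5 dark arrays simulated as unchanged and that array shared, the median ratio was 0.065 on average and 0.098 at most in 20 simulations. With the pil5 and red differences taken from different numbers, so that no array was shared, it ran from 0.54 to 1.01, so the size of the part is not settled.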
